A study of Mus musculus with 12 samples.

How the data were processed

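RNA was sequenced from 12 mouse tissue libraries, 6 labelled wild type and 6 labelled hM3Dq/Villin-Cre, which carry a designer Gq-coupled receptor together with a Cre recombinase driven in the intestinal epithelium. The tissue of every library was labelled small intestine, and clozapine N-oxide (CNO) had been injected at 200 μg/kg in both groups, per the labels. RNA was purified on silica columns and libraries were made with the SMARTer mRNA-Seq kit, per the labels' protocols. The authors deposited 1 table of FPKM values, which are reads scaled to gene length and to the counted reads of the library, with 21878 genes in rows and a column for each of the 12 libraries. Reads were placed on the GRCm38 (mm10) mouse genome, per the submitters' processing notes. The aligner, the counting program, its strand setting and its treatment of reads shared between similar genes are not given in the sources used here. Genes that overlap a neighbour on the other strand, and ribosomal protein genes with their many processed pseudogenes, therefore carry an uncertainty that cannot be sized from the table. Group membership came from the genotype label of each sample. The labels give no batch, sex or pairing, and replicate numbers follow the order of the samples only.

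Depth was worked out from the FPKM values themselves, since every value of a gene is a whole multiple of what 1 read is worth in its library. All 196408 values above 0 (100%) came out as whole reads within a tolerance of 0.0001 of a read. The reads of 75 genes shared a common factor, so that their length and reads are known only up to that factor, and 3946 genes were listed at 0 in every library. The 6 wild type libraries held 18416498, 18376486, 17832008, 18727892, 18703977 and 19510013 counted reads, and the 6 hM3Dq/Villin-Cre libraries held 18976018, 17925969, 18234040, 18118315, 18643203 and 18260569. At these depths 3 reads of a gene of 2 kb amount to an FPKM of 0.0769 to 0.0841. Such limits cover counting error only, because PCR copies were not marked by molecular identifiers.

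Values were analysed as log2(FPKM + 1) for the 12782 genes with an FPKM of at least 0.5 in at least 6 libraries, so fold changes of low genes are understated. The groups were compared with limma (version 3.58.1, R 4.3.3), a linear model with moderated variances that follow an intensity trend. Tests were two-sided and adjusted p-values are Benjamini-Hochberg values, with a threshold of 0.05. Of the 46 gene lists written from textbook knowledge, 44 had at least 3 tested members and were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Single values were compared by an exact two-sided permutation test over all 462 splits of the libraries into 6 and 6, which can give no p below 0.00216. Gene coordinates are 1-based and come from GENCODE release M21 on GRCm38, which also gave the GC content of exons. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

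The groups, the test, the lists and the alternatives to them were fixed before the data were examined, together with the rule for naming genes. By that rule, the 12 largest rises and 12 largest falls past the threshold with a mean FPKM of at least 1 were named, leaving out predicted gene symbols. Up to 4 members with the smallest p were added from each list with a member past the threshold over all genes or over the list alone. Chrm3, Vil1, Fos, Egr1, Nr4a1, Dusp1, Areg, Cxcl1, Ptgs2, Tph1, Cftr and Muc2 were named in any case. Several alternatives were chosen after seeing the data. These were a limma voom test on the recovered reads, 2 lists of genes of the small and large intestine, and a comparison without wild type replicates 1 and 5. The removal of a trend with gene length and GC content was also added, with a natural spline of 5 degrees of freedom for each, fitted per library. The planned quasi-likelihood count test was not run because the table holds no counts. No term for sex was fitted, since the labels give no sex and the Y-linked gene Ddx3y had at most 3 reads in any library.

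The main test was tested on simulated reads for this comparison, drawn for the real genes with the real depths and the real spread of each gene. Genes were drawn independently, without the structure that the real genes share across libraries, so the rates below may not hold for the real data. Of the genes set to change, it recovered 40.3% of those set to 1.5-fold (27 of 67), 70.1% at 2-fold (47 of 67) and 93.9% at 4-fold (62 of 66). It called 5 unchanged genes among the 12678 simulated. A linear trend with GC content, equal in all libraries of 1 group, was also planted, without a trend in gene length. Then 1433 unchanged genes of 12321 were called before the removal of a length and GC trend and 4 after it. Of 199 changed genes, 137 were called after it against 158 before.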

Results

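Bulk RNA sequencing was carried out on 12 mouse libraries labelled as small intestine. The designer receptor hM3Dq was built from the human muscarinic M3 receptor. It couples to Gq proteins, which release calcium inside the cell, and it answers to CNO in place of acetylcholine. Villin-Cre restricts it to the intestinal epithelium. The series describes a model of irritable bowel syndrome driven by the receptor CHRM3, with sampling 0.5 h after its induction. The comparison asks which transcripts differ between 6 libraries labelled hM3Dq/Villin-Cre and 6 labelled wild type, both after CNO at 200 μg/kg. The samples hold no group without CNO and none with Cre alone. Stimulation of the receptor can therefore not be told from other effects of the genotype. Depth was even, at 17832008 to 19510013 counted reads per library. The labels do not say that the libraries of a group came from separate animals, so p-values measure the spread between these libraries only.

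Among the genes that rose in libraries labelled hM3Dq/Villin-Cre were Cftr and Slc4a7, ion transporters of epithelial fluid secretion, and Idi1 and Hmgcs1, enzymes of cholesterol synthesis. Among those that fell were 10 of 43 ribosomal protein genes. The changes were modest. In all, 215 genes rose and 193 fell among 12782 tested (limma, adjusted p of 0.0422 to 0.0497). The median size of these changes was 0.46 on the log2 scale, and 9 rises and 2 falls reached 2-fold. After a trend with gene length and GC content was removed limma called 0 genes (844 higher and 992 lower at an unadjusted p under 0.05; voom without that removal called 149 rises and 100 falls), and leaving out any 1 of 7 libraries left at most 1 gene called. Cftr, the chloride channel through which crypt cells secrete fluid (chromosome 6, 18170687 to 18322768, GRCm38), rose from an FPKM of 12.4 ± 3.71 to 22.6 ± 4.31 (SD, n = 6 each). This was a log2 change of 0.85 ± 0.20 (SE; limma adjusted p = 0.0456), and the gene was higher in each of the 6 hM3Dq/Villin-Cre libraries than in any wild type library. Early response genes such as Fos and Egr1, which cells switch on within minutes of a calcium signal, did not follow the labels.

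The receptor itself could not be followed directly, because the table lists mouse Chrm3 and no separate human sequence. Chrm3 (chromosome 13, 9875486 to 10360847) had an FPKM of 3.17 ± 1.74 in the wild type and 4.49 ± 2.37 in the hM3Dq/Villin-Cre libraries (SD, n = 6 each; exact permutation p = 0.264). Vil1, the gene whose promoter drives Cre, had an FPKM of 302 ± 33.9 and 284 ± 15.1 (SD, n = 6 each; exact permutation p = 0.279). Among 27 tested genes of muscarinic and Gq signalling, none passed the limma threshold (7 higher and 2 lower at an unadjusted p under 0.05, none with voom, 1 with the exact permutation test per gene). Of all 12782 tested genes, 1828 were higher and 1761 lower at that unadjusted p. The list had a camera adjusted p of 0.120 in the higher direction (adjusted p = 0.981 with an estimated correlation). Its mean log2 level was 3.46 in wild type and 3.58 in hM3Dq/Villin-Cre libraries (exact permutation p = 0.0108, adjusted p = 0.249 over the lists).

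Early response genes fell into a high and a low set of libraries, and each set held libraries of both labels. Nr4a1, a nuclear receptor induced by calcium, had FPKM values of 347 and 565 in wild type replicates 3 and 5 but 2.79 to 9.67 in the other 4 wild type libraries. In the hM3Dq/Villin-Cre libraries it lay at 243 to 410 in replicates 2 to 5, and at 5.94 and 2.30 in replicates 1 and 6. Areg, a ligand of the EGF receptor, showed the same division, with 590 and 456 against at most 31.2 in wild type, and 632 to 740 against 23.6 and 24.8 in hM3Dq/Villin-Cre libraries. Fos, Egr1 and the MAP kinase phosphatase Dusp1 divided the libraries in the same way. Between the labelled groups, exact permutation tests gave p = 0.623 for Fos, 0.545 for Egr1, 0.513 for Nr4a1, 0.511 for Dusp1 and 0.106 for Areg (5 genes, 6 libraries per group).

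**Figure D1:**
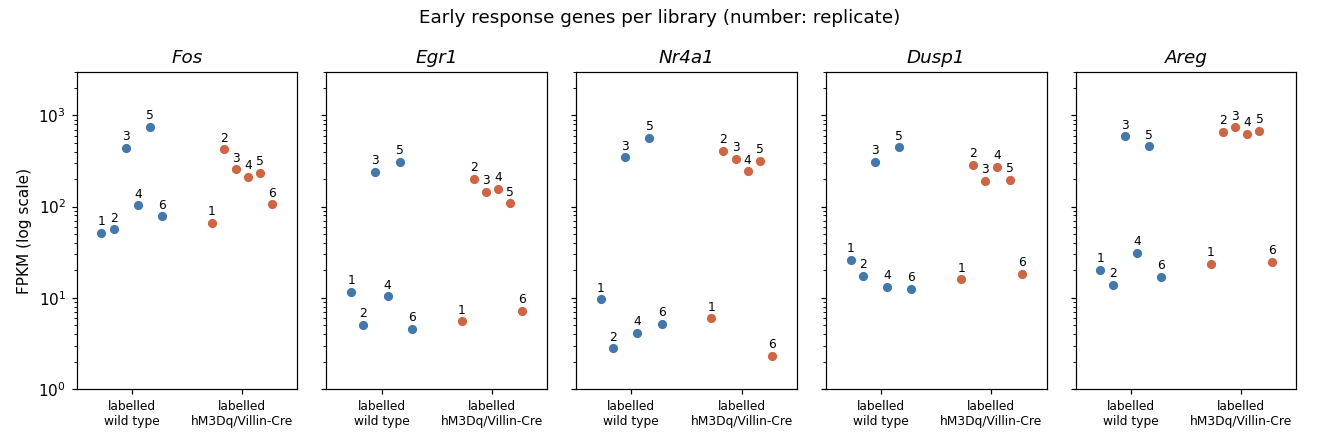
FPKM of Fos, Egr1, Nr4a1, Dusp1 and Areg in each library on a logarithmic axis, by labelled group, with replicate numbers beside the points. Wild type replicates 3 and 5 lie with hM3Dq/Villin-Cre replicates 2 to 5, and hM3Dq/Villin-Cre replicates 1 and 6 lie with the other wild type libraries.

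None of 29 immediate early transcription factors passed the limma threshold, over all genes or adjusted over the list alone. Voom and the exact permutation test per gene called none, and 2 were higher at an unadjusted p under 0.05. Their median log2 change was 0.37, 25 of the 29 were higher in hM3Dq/Villin-Cre libraries, and the camera adjusted p was 0.120 (adjusted p = 0.981 with an estimated correlation). With the length and GC trend removed the median was 0.51 and the camera adjusted p 0.00210 (adjusted p = 0.959 with an estimated correlation). The mean log2 level of this list ran from 3.58 to 4.02 in the 6 low libraries and from 5.68 to 6.19 in the 6 high ones. Of 31 early response feedback regulators limma and voom called none as single genes, with 2 higher at an unadjusted p under 0.05. For that list camera gave an adjusted p of 0.0412 for a median of 0.53 (adjusted p = 0.981 with an estimated correlation). Of 16 calcineurin and calcium response genes, Homer1 alone rose, also adjusted over the list alone, by 0.77 ± 0.17 (SE; limma adjusted p = 0.0443). The calcineurin subunits Ppp3ca, Ppp3cb and Ppp3r1 had log2 changes of 0.33, 0.43 and 0.25 that did not pass. That list had a camera adjusted p of 0.0476 (adjusted p = 0.981 with an estimated correlation). Of 15 EGF receptor ligands and growth factors, the ligand Btc alone rose, by 0.90 ± 0.21 (SE; limma adjusted p = 0.0479) and also adjusted over the list alone. Ereg (1.89 ± 0.92), Nrg1 (0.35) and Vegfa (0.24) did not pass. The list had a camera adjusted p of 0.0412 (adjusted p = 0.981 with an estimated correlation). With TPM scaling or median ratio scaling these last 3 lists no longer passed.

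Fluid secretion genes moved in part. Of 29 tested, Cftr and the bicarbonate transporter Slc4a7 (log2 change 0.91 ± 0.20, SE; limma adjusted p = 0.0427) rose. Adjusted over the list alone there were 3 rises, the third being Slc12a2, the basolateral cotransporter for chloride entry (FPKM 33.0 ± 10.8 and 52.1 ± 6.86, SD, n = 6 each; limma adjusted p = 0.0612 over all genes). The scaffold gene Slc9a3r1 had a log2 change of −0.40 that did not pass, and the list as a whole had a median of −0.01 and a camera adjusted p of 0.911 in the other direction. Of 24 genes of serotonin, histamine and prostanoid mediators limma and voom called none (4 higher and 2 lower at an unadjusted p under 0.05), and the exact permutation test per gene called 2. Tph1, the serotonin-making enzyme of enterochromaffin cells, had a log2 change of 0.56 ± 0.31 (SE; limma adjusted p = 0.253). The goblet cell mucin Muc2 had 0.18 ± 0.44 (SE; limma adjusted p = 0.814).

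Cholesterol synthesis genes were higher as a list, with a median log2 change of 0.36 over 22 genes and a camera adjusted p of 0.0101 (adjusted p = 0.981 with an estimated correlation). Idi1 (1.06 ± 0.25, SE) and Hmgcs1 (0.79 ± 0.19, SE), both enzymes of the mevalonate pathway, rose over all genes and adjusted over the list alone, while Stard4 at 0.46 and Dhcr7 at −0.25 did not pass. Outside the lists, the largest rises were those of Ccnl1 (1.29), a cyclin that works in splicing, March7 (1.26), Gpcpd1 (1.25), Trp53inp1 (1.16), a p53 target, and the RNA helicase gene Ddx3x (1.15). They were followed by Wsb1 (1.10), Lysmd3 (1.08), Rasef (1.01), Clca3a1 (0.99), the hypoxia-inducible factor Hif1a (0.99) and the heme-responsive repressor Bach1 (0.96), each with a limma adjusted p between 0.0422 and 0.0497. Clca3a1 has close relatives in the genome, and reads shared with them could have been counted either way. The glucocorticoid-induced factor Klf9 rose by 0.76 ± 0.14 (SE; limma adjusted p = 0.0422), the clock gene Clock by 0.74 and the chaperone gene Dnajb4 by 0.73. Each was the sole rise in its list (18, 19 and 20 tested genes), also adjusted over the list alone. Of the other members named there, Tsc22d3 (−0.49), Hsd11b2 (−0.55), Nr3c1 (0.51), Dbp (−1.12), Tef (−0.67), Nr1d2 (0.55), Hspa4l (0.66) and Stip1 (−0.31) did not pass.

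Ribosomal protein genes were lower: 10 of 43 fell over all genes and 26 adjusted over the list alone. Their median log2 change was −0.22, with a camera adjusted p of 3.07e-10 (adjusted p = 0.981 with an estimated correlation). Rpl18 fell from an FPKM of 563 ± 56.0 to 440 ± 26.0 (SD, n = 6 each). Rpl8 fell from 1072 ± 87.2 to 852 ± 27.0 and Rps16 from 929 ± 75.2 to 748 ± 30.8 (SD, n = 6 each). After quantile normalization the ribosomal median was −0.06 with a camera adjusted p of 0.649. With the length and GC trend removed it was −0.04 with a camera adjusted p of 0.0315 (adjusted p = 0.959 with an estimated correlation), and limma called none of the 10 genes. Of 32 nuclear genes of oxidative phosphorylation 1 fell over all genes, Ndufa8, with a log2 change of −0.26 ± 0.06 (SE; limma adjusted p = 0.0479), and 6 fell adjusted over the list alone. Cox4i1 (−0.31), Ndufb7 (−0.31) and Ndufb9 (−0.28) did not pass over all genes. The camera adjusted p of that list was 0.0101 (adjusted p = 0.981 with an estimated correlation) for a median of −0.09, which turned to 0.02 after quantile normalization. Among 23 hypoxia and glycolysis genes the glycolytic enzyme gene Pfkl fell (−0.40 ± 0.09, SE; limma adjusted p = 0.0444), also adjusted over the list alone, and Aldoa (−0.33), Eno1 (−0.32) and Hk1 (−0.25) did not pass. The cochaperone gene Fkbp4 fell by 0.39 on the log2 scale (limma adjusted p = 0.0456).

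Spp1, Ccl3 and Acod1 had the largest falls. Spp1 (osteopontin; chromosome 5, 104435118 to 104441050) fell from an FPKM of 8.36 ± 0.65 to 1.84 ± 2.01, a log2 change of −1.99 ± 0.34 (SE; limma adjusted p = 0.0422). The chemokine gene Ccl3 fell from 3.48 ± 0.79 to 0.86 ± 0.77, and Acod1, the itaconate-making enzyme, from 1.27 ± 0.43 to 0.25 ± 0.27 (SD, n = 6 each). Of 22 chemokine and cytokine genes only Ccl3 fell over all genes, and 2 adjusted over the list alone, Ccl3 and Ccl4 (−0.78 ± 0.22, SE), while 17 of the 22 were higher and the camera adjusted p was 0.911. Ccl7 (1.17 ± 0.75, SE), Cxcl1 (0.57) and Ptgs2 (1.01) did not pass. The DNA replication factor Cdt1 fell by 0.60 on the log2 scale and Uhrf1, which maintains DNA methylation, by 0.48. Other named falls were Pddc1 (−0.53), Igsf23 (−0.51), Psmg3 (−0.49), Ankrd54 (−0.49), Cuta (−0.47) and Mettl13 (−0.47).

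Markers of cell types and of position along the small intestine did not pass. The position lists, for duodenum and jejunum and for ileum, had 6 and 10 tested genes. They cannot show whether position within the large intestine was equal. Of 291 tested members of 22 lists, limma called none over all genes, as did voom and the exact permutation test per gene. There were 15 higher and 7 lower at an unadjusted p under 0.05. Adjusted over the list alone the enterocyte peptidase Dpp4 rose (0.58 ± 0.15, SE), and Anpep (−0.26), Dgat2 (−0.47) and Mgam (0.51) did not pass. The 15 macrophage and dendritic cell markers had a median log2 change of −0.09 and a camera adjusted p of 0.911, and the 25 proliferation genes a median of 0.00.

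Of 12 genes of the small intestine, most had few or no reads. Sis, the sucrase of small intestinal enterocytes, had 10 reads over all libraries together, and Lct, Apoa4 and Fabp1 had 27, 1 and 13. Others were read at higher levels, with FPKM values of 3.50 to 10.2 for Fabp6, 0.0932 to 3.12 for Slc10a2 and 0.551 to 30.98 for Lyz1, a Paneth cell gene. Genes of the large intestine were abundant: Car1 lay at FPKM values of 241 to 908, Aqp8 at 374 to 1115, Mptx1 at 5227 to 23977, and the distal factor Hoxb13 at 49.7 to 411. Over lists chosen after seeing the data, 0 of 12 small intestine genes and 9 of 10 large intestine genes reached a median FPKM of 10.

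**Figure D2:**
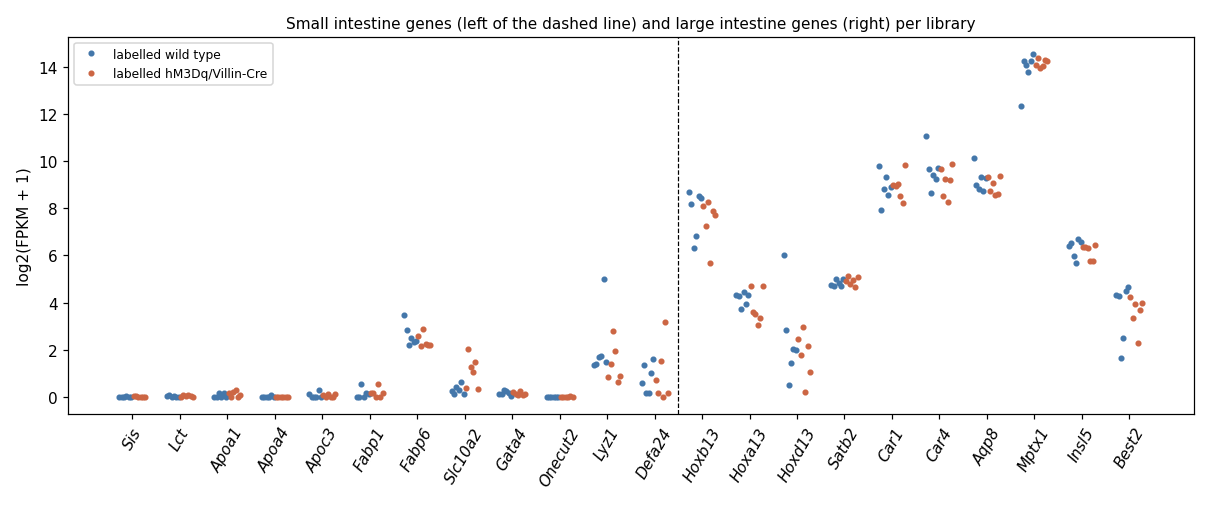
Level of 12 small intestine genes and 10 large intestine genes in each library, as log2(FPKM + 1), with libraries labelled wild type in blue and hM3Dq/Villin-Cre in red. Most small intestine genes lie near 0 in both groups, whereas all large intestine genes except Hoxd13 had a median FPKM of at least 10.

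The change of a gene between the labelled groups followed its length and GC content. Genes that rose had a median length of 6820.5 bp and a median exon GC content of 42.5%, genes that fell 1372 bp and 56.0%, and genes not called 3341 bp and 50.2%. Across genes, which are not independent replicates, Spearman's rho between the log2 change and GC content was −0.626, and 0.381 with length. The sum of FPKM values was 484110 ± 8197 in wild type and 456910 ± 8762 in hM3Dq/Villin-Cre libraries, without overlap (SD, n = 6 each; exact permutation p = 0.00216, the smallest possible). Rescaling each library to the same sum (TPM) gave 539 rises and 71 falls in place of 215 and 193, and median ratio scaling gave 454 and 234.

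**Figure D3:**
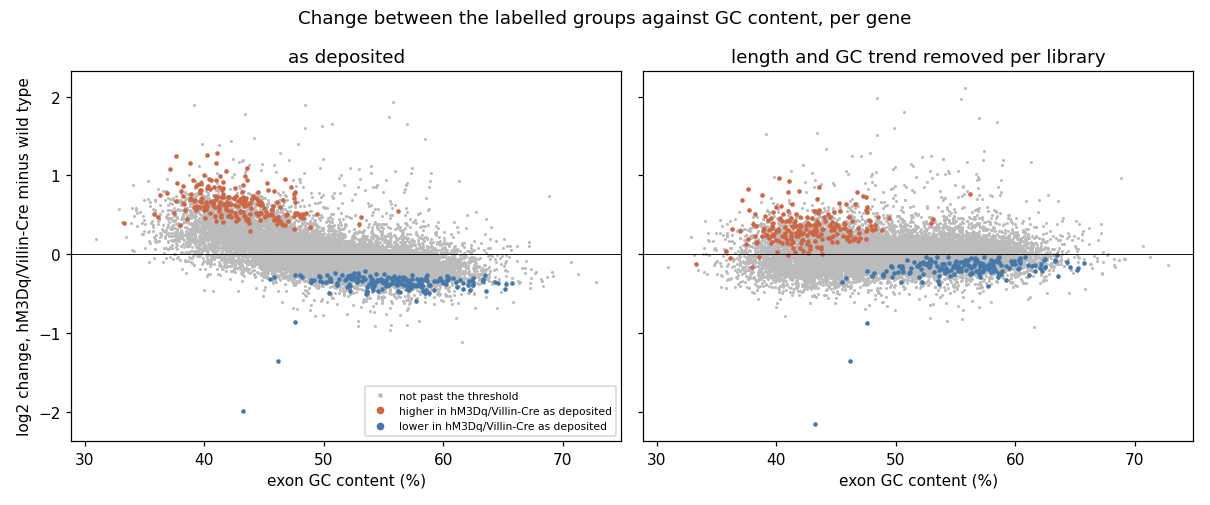
Log2 change of each of 12423 genes between the labelled groups against its exon GC content in percent, as deposited (left) and after the length and GC trend was removed from each library (right). Genes called higher (red) have a median GC content of 42.5% and genes called lower (blue) 56.0%; the colours are those of the calls as deposited in both panels.

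After removal of that trend, limma called 0 genes (844 higher and 992 lower at an unadjusted p under 0.05; voom on the uncorrected reads called 149 rises and 100 falls). After the removal Cftr had a log2 change of 0.47 ± 0.12 (SE; limma adjusted p = 0.142) and Homer1 0.29 ± 0.21 (SE; limma adjusted p = 0.570). The changes of Slc4a7, Idi1, Hmgcs1 and Btc became 0.51, 0.80, 0.55 and 0.56, none past the threshold. Leaving out 1 library at a time left at most 1 gene called for 7 of the 12 libraries, wild type replicates 1, 4 and 6 and hM3Dq/Villin-Cre replicates 1, 2, 4 and 5.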

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

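The tests of this part were chosen after the results were seen, except the search for libraries that stand apart and the count over other splits of the libraries, which were planned.

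In 15 of 256 groups of 6 libraries (80 named genes, 44 lists and 4 measures of depth, each in both groups) the highest or lowest library stood apart from the other 5 by Dixon's criterion. Chance alone gives about 1 in 20, or 12.8 groups. Wild type replicate 1 accounted for 7 of them, with FPKM values of 614 for Aldoa, 97.8 for Dbp and 268 for Muc2. Its mean log2 levels were 3.66 for the circadian clock list, 7.25 for goblet cell genes, 4.40 for Paneth cell genes and 3.48 for stem cell genes. Wild type replicate 5 stood apart with FPKM values of 5.47 for Bach1, 4.29 for Nr1d2 and 1074 for Rps16, and wild type replicate 3 with 60.6 for Wsb1. Replicate 6 of hM3Dq/Villin-Cre stood apart with 6.35 for Dnajb4, 49.0 for Pfkl and a mean log2 level of 2.37 for the serotonin, histamine and prostanoid list, and replicate 3 with 19.1 for Mgam.

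Early response genes were high in 2 libraries labelled wild type and low in 2 labelled hM3Dq/Villin-Cre, with a gap of 1.66 in the mean log2 level of the immediate early list where the next widest gap was 0.23. When each tested gene was asked which 6 libraries held its highest values, the most common answer among the 462 splits, for 1021 genes against 27.7 by chance, exchanged exactly these 2 libraries of each group. The labels themselves separated 566 genes without overlap, which put the labelled split at rank 3. A length and GC trend also differed between the labels, with some overlap for GC content, so these genes cannot decide on library names exchanged after the libraries were made. An exchange of animals or genotypes before that step may be the cause. It cannot be told apart from an untested response to CNO that varies between mice, because reads of the human receptor were not analysed here. A response through the receptor would leave wild type replicates 3 and 5 unexplained if their labels are right. Mouse Chrm3 gave an exact permutation p of 0.264 between the labelled groups, which an exchange could also give, so it cannot decide. Its FPKM was 3.28 to 8.85 in the 6 libraries with high early genes and 0.900 to 3.60 in the 6 low ones, with overlap. Stress during tissue handling cannot be told apart either, since 5 of the 6 libraries with the highest mean of the heat shock list were also among the 6 with the highest early genes, while wild type replicate 4 had high heat shock (5.80) with low early genes and wild type replicate 5 the reverse (5.10).

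Genes called between the labelled groups differed in GC content and length, and a trend with GC content and gene length in each library is a candidate explanation for most of the calls. Its removal covered the 12423 tested genes with both a length and a GC content, which left out some of the 408, such as Pddc1. Once the trend was removed 0 genes were called. For the called genes covered, the median size of the log2 change went from 0.462 to 0.221 and its median SE from 0.103 to 0.0808, although not every change shrank. Cftr shrank to 0.47 and Homer1 to 0.29, while Spp1 at −2.16, Ccl3 at −1.36, Acod1 at −0.87 and Klf9 at 0.72 stayed near their uncorrected sizes; these 4 missed the threshold with adjusted p-values of 0.108, 0.130, 0.130 and 0.108, where the smallest over all genes was 0.0842. A library batch that follows the labels cannot be told apart from the genotype, since the sum of FPKM values differed between the labelled groups with an exact permutation p of 0.00216 and the labels give no batch. A change in long transcripts of low GC content caused by the receptor is the biological alternative, and it was not tested.

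The planned count over 100 splits argues against chance for the number of genes called between the labelled groups but does not exclude it. Only 1 of the 100, the labelled one, gave as many as 408 genes, and the highest other of those drawn gave 301. The draw from 462 splits missed both splits that separate more genes than the labels do. Fitted afterwards, these called 1805 genes (wild type replicates 3 and 5 exchanged with hM3Dq/Villin-Cre replicates 1 and 6) and 832 genes (wild type replicate 2 exchanged with hM3Dq/Villin-Cre replicate 3). The drawn splits with 301 and 257 genes exchanged wild type replicate 3 with hM3Dq/Villin-Cre replicate 1 and replicate 6, respectively. Counts above that of the labels point to a structure of the samples that the labels do not follow. The split with 832 genes matched the GC trend of each library. Its side with wild type replicate 2 held the 6 libraries with the lowest slopes on GC content. These slopes were −0.135 to −0.05 (log2 per SD of GC content), against 0.008 to 0.298 on the other side.

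Small intestine genes were mostly near 0 and large intestine genes abundant in libraries labelled small intestine. A minor share of large intestine in small intestine tissue is argued against by Sis, with 10 reads over the 12 libraries, since its mRNA is abundant in the enterocytes of that tissue. Tissue from the large intestine is a candidate explanation: 0 of 12 small intestine genes and 9 of 10 large intestine genes had a median FPKM of at least 10. No biological explanation was tested.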

How the results depend on the processing

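The alternatives below were planned, except voom on the recovered reads, the removal of length or GC trends and the comparison without wild type replicates 1 and 5, which were chosen after seeing the data. No paired analysis was possible because the labels give the groups no shared numbers. The counts of rises and falls, 215 and 193, were 94 and 114 with a pseudocount of 0.1, 138 and 144 with 0.5, 22 and 56 without a filter on low values, 539 and 71 with TPM scaling, and 454 and 234 with median ratio scaling. They were 129 and 98 without the variance trend, 1039 and 1569 with library weights, 250 and 316 with the exact permutation test per gene, 1080 and 947 at an adjusted p under 0.1, and 9 and 2 with a change of at least 2-fold. The cause of these shifts was not tested, except that the last 2 follow from the threshold. All 566 genes called by the exact permutation test were at its smallest possible p of 0.00216 (adjusted p = 0.0489). They are the genes that the labels separated without overlap. Voom gave 149 and 100, of which 247 were among the 408. Removing the length and GC trend, or either alone, gave 0 and 0 with limma (844 and 992, 1404 and 1777 for length, and 1103 and 1164 for GC at an unadjusted p under 0.05). Leaving out wild type replicates 1 and 5 together also gave 0 and 0 (1101 and 1492), where fewer libraries were compared. With single libraries left out, rises ranged from 0 to 729 and falls from 0 to 362. No gene was called without wild type replicate 1 (1532 and 1782 at an unadjusted p under 0.05), 4 (1833 and 1429) or 6 (1667 and 1503). The same held without hM3Dq/Villin-Cre replicate 1 (1531 and 1999), 2 (1549 and 1364) or 5 (1510 and 1243), and 1 fall was left without replicate 4 (1704 and 1392). The highest counts came without wild type replicate 2. The others gave 97 and 96 (without wild type replicate 3), 72 and 39 (5), and, for hM3Dq/Villin-Cre, 167 and 116 (3) and 67 and 52 (6). The immediate early list, with a median of 0.37, passed with 0.439 after quantile normalization, 0.511 with both trends removed, 0.508 with the GC trend removed and 0.605 without wild type replicates 1 and 5. The list passed under no alternative with an estimated correlation (lowest adjusted p = 0.931 with an estimated correlation, without hM3Dq/Villin-Cre replicate 1). Its median ranged from 0.258 to 0.606 with single libraries left out, and it passed without wild type replicate 3 or 5 or hM3Dq/Villin-Cre replicate 1 (0.595) or 6 (0.533). These are the libraries whose early genes lay against their labels, so leaving any of them out raises the labelled difference by construction. Wild type replicate 5, left out above together with replicate 1, is among them. The ribosomal list no longer passed after quantile normalization, at −0.0578, or with an estimated correlation (adjusted p = 0.981), at −0.221. It passed at −0.0446 with both trends removed (adjusted p = 0.0315, and adjusted p = 0.959 with an estimated correlation), −0.101 with length and −0.14 with GC removed, and its median ranged from −0.24 to −0.194 with single libraries left out. The oxidative phosphorylation list turned to 0.0152 after quantile normalization and, by camera's direction, at −0.0162 with the length trend removed. Of 39 named genes past the threshold, 9 were lost with TPM scaling, 6 with quantile normalization and 0 with median ratio scaling. Voom lost 14 and the exact permutation test 15. None changed sign, which the exact test could not show because it used the same log2 changes. Fry's directional test passed 1 list, the ribosomal proteins, and its mixed test 2.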

Other observations

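All 11 tested antigen presentation genes of MHC class II were lower in libraries labelled hM3Dq/Villin-Cre, with a median log2 change of −0.46. The camera adjusted p was 0.120 (adjusted p = 0.981 with an estimated correlation). The wild type libraries with the highest mean log2 levels of that list were replicates 5 (5.80) and 1 (5.07), and without both the median was −0.07. Replicate 5 also had the highest mean of the B cell and plasma cell list, 4.95, where the other 11 libraries had 3.13 to 4.25. Interferon response genes had mean log2 levels from 4.10 to 5.40, and the labelled groups had means of 4.78 ± 0.52 and 4.87 ± 0.38 (SD, n = 6 each; exact permutation p = 0.723). Of the large intestine genes, Hoxd13 varied most, at an FPKM of 63.4 in wild type replicate 1. It lay at 0.41 to 6.14 in the other wild type libraries and at 0.16 to 6.74 in hM3Dq/Villin-Cre libraries. Replicate 1 of the wild type also had the highest mean log2 levels of smooth muscle genes (6.77) and enteric neuron genes (2.74). Close to it was hM3Dq/Villin-Cre replicate 3, with 6.70 and 2.67.

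Spp1 stood out among genes of similar depth by how evenly it was read in the wild type libraries. Its reads there were 263, 289, 241, 237, 246 and 269, an index of dispersion of 1.53 where Poisson counting gives 1. Of 1061 tested genes with a mean within 1.2-fold of it, 33 were as even or more so (median index 12.7). Spp1 was chosen for its fall past the threshold, which favours genes with little spread within a group, so this rank is a description only. In the hM3Dq/Villin-Cre libraries it had 14, 17, 13, 145, 123 and 23 reads, an index of 66.9. Ccl4 had an index of 0.76 in the wild type and 10.6 in the hM3Dq/Villin-Cre libraries, Ccl3 2.61 and 10.1, and Acod1, less even in the wild type, 7.02 and 14.2.

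The first principal component of all tested genes, with 38.5% of the variance, put wild type replicates 3 and 5 (27.2 and 19.1) on the side of hM3Dq/Villin-Cre replicates 2 to 5, and hM3Dq/Villin-Cre replicates 1 and 6 (−26.1 and −24.1) on the side of the other wild type libraries. The second, with 26.6%, set wild type replicates 5 and 1 apart, at 46.0 and 30.9. The library nearest to wild type replicate 3 by correlation was hM3Dq/Villin-Cre replicate 4, and the library nearest to both hM3Dq/Villin-Cre replicates 1 and 6 was wild type replicate 2.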
